A study of Mus musculus with 15 samples.

How the data were processed

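RNA from mouse corpus callosum had been sequenced in 15 libraries, 3 in each of 5 groups: the saline injection site of sham-operated mice (Sham_Ipsil), the injured tissue after lysophosphatidylcholine (LPC_Ipsil), the tissue contralateral to it (LPC_Contra), the injured tissue after L-NIO (LNIO_Ipsil) and the tissue contralateral to it (LNIO_Contra). Injured and contralateral tissue was taken on day 4, per the labels' protocols, which name no separate day for sham tissue. TRIzol extraction, ribosomal RNA depletion, poly(A) purification and paired-end NovaSeq sequencing are named there too. No label says whether the libraries of a group came from separate mice, so by the labels alone p-values measure the spread between these samples, which may be technical.

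The deposited count table holds whole numbers of reads per gene symbol for each library, and the deposited FPKM table holds the authors' fragment counts scaled by gene length and library size for the same genes. HISAT2 2.2.1, R 4.4.2 and the build GRCm39 are named per the submitters' processing notes. The counting program, its strand setting and the annotation are not given in the sources used here, so genes that overlap, lie antisense to another gene or have a near-identical copy are uncertain. Both tables give symbols without other identifiers, 74 entries repeat a symbol already used, and no coordinates are printed. All 15 columns of each table were matched to a library by model, side and number, and 0 columns were left unmatched.

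The table held 33321 genes. Library totals ran from 14896445 to 20916606 counts. Expression is given as CPM, counts scaled to the library total, and 19786 to 20696 genes were detected per library. Replicate pairs of a group were compared by chi-square over genes with at least 20 counts. The statistic per degree of freedom ran from 10.1 to 63.7, so no pair looked like the same library deposited again.

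Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersion, trimmed mean of M-values (TMM) scaling (factors 0.966 to 1.06) and filterByExpr by group (minimum count 10, minimum total 15). This left 16795 tested genes. One model held all 15 libraries with a mean per group and no block, and the common dispersion was 0.0453. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. CPM values are TMM-scaled means over 3 libraries with their SD, and log2 fold changes carry their standard error (SE), taken as the size of the fold change divided by the square root of F. Group comparisons were LPC_Ipsil, LNIO_Ipsil, LPC_Contra and LNIO_Contra each against Sham_Ipsil, LNIO_Ipsil against LPC_Ipsil, each injured side against its contralateral side, LNIO_Contra against LPC_Contra, and the interaction of model and side. The design, the lists, the naming rule and most of the other settings tested were fixed before the data were examined.

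Fixed gene lists, 40 in all, covered mature oligodendrocytes and myelin, oligodendrocyte precursors, differentiating oligodendrocytes, homeostatic and damage-associated microglia, infiltrating monocytes, border macrophages, neutrophils, T cells, natural killer cells, B and plasma cells, dendritic cells, astrocytes, reactive astrocytes, endothelium, pericytes and smooth muscle, fibroblasts, neurons, cortical excitatory neurons, striatal neurons, neuroblasts, ependyma, choroid plexus and red blood cells. The others covered mitochondrially encoded genes, proliferation, cholesterol biosynthesis, lipid efflux and storage, interferon response, MHC class I, MHC class II, complement, cytokines, chemokines, hypoxia, angiogenesis, the integrated stress response, oxidative stress, immediate early genes, and matrix and scar. Several immune lists share genes that microglia also express. Lists with at least 3 tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and by fry, which asks whether a list's genes move one way on balance.

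Genes are named by a rule. In comparisons among Sham_Ipsil, LPC_Ipsil and LNIO_Ipsil the 8 largest increases and the 8 largest decreases were named among called genes with an average log2 CPM of at least 1 and no overlap between the groups, and in comparisons with a contralateral group the 4 largest of each. From each list described up to 4 tested members with the smallest adjusted p in that comparison were named. Genes named always included Mbp, Mog, Pdgfra, Gpr17, Gfap, Aif1, P2ry12, Trem2, Cd68, Apoe, Spp1, Cst7, Nos3, Hmgcs1, Ccl2, Cd3e, Snap25, Cldn5 and Col1a1. The rule allows leaving out predicted genes and immunoglobulin or T cell receptor segments, and 0 had to be left out. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

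Other settings fixed at that point were DESeq2 median-of-ratios factors in edgeR, no filter beyond 1 count, a stricter filter (CPM of at least 1 in at least 3 libraries), the DESeq2 1.42.0 Wald test, a model of only the groups compared, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 0.5 in at least 3 libraries, and leaving out each library of the groups compared. Settings chosen after seeing the data were limma voom with sample quality weights and leaving out LPC_Ipsil replicate 3 or LPC_Contra replicate 2 where they lie outside a comparison, and leaving out single libraries from the comparison of the L-NIO and LPC responses. The block was model and number together over 12 libraries for comparisons of sides and their interaction, and number as an additive term over 15 libraries elsewhere. To check the pairing, the deviations of log2 CPM (prior count 2) from the group means were correlated between same-numbered injured-side and contralateral libraries. In the L-NIO groups they correlated at 0.599, 0.356 and 0.249, all over 0.1, so their numbers were taken to pair the libraries, a pairing that comes from the data and not from the labels. A differently numbered pair, LNIO_Ipsil replicate 3 and LNIO_Contra replicate 2, also passed 0.1 (0.195). Values printed for the L-NIO sides still come from the fit without a block, with the count under the block beside them.

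The test was tested on simulated data for LNIO_Ipsil against Sham_Ipsil over 16644 genes, with 200 changed genes. It called 53 of 67 genes changed 2-fold (79.1%), 64 of 67 changed 4-fold (95.5%) and 66 of 66 changed 8-fold (100%), with 10 other genes called and 0 in unchanged comparisons. In the simulation every library of a group follows one mean, which real libraries need not do. Changed genes were drawn only above a floor of mean CPM, so the shares recovered say nothing of genes at low CPM. The neutrophil, natural killer, B and plasma cell, and dendritic lists had under 3 tested members and were not tested as lists. Ccl2 and Cd3e did not pass the count filter and are given as CPM.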

Results

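Gene expression was measured in mouse corpus callosum, the white matter tract that joins the hemispheres, after 2 kinds of focal injury. Lysophosphatidylcholine (LPC) is a membrane-dissolving lipid used to strip myelin, and L-NIO is an inhibitor of endothelial nitric oxide synthase used to make a white matter stroke (WMS). Injured tissue (LPC_Ipsil, LNIO_Ipsil) and tissue contralateral to it (LPC_Contra, LNIO_Contra) were taken on day 4, and the saline injection site of sham-operated mice (Sham_Ipsil) was the control. Each group had 3 libraries, 15 in all, with 14896445 to 20916606 counts per library and 16795 genes tested.

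The leading principal component held 31.6% of the variance and ran from LPC_Ipsil replicate 1 (77.2) and replicate 2 (50.6) through the LNIO_Ipsil libraries (12.7 to 34.3). LPC_Ipsil replicate 3 lay at -11.3, among the sham and contralateral libraries. Its score for damage-associated microglia, the mean over list members of log2 CPM relative to sham, was 0.256, while the other LPC_Ipsil libraries scored 3.80 and 3.10 and the highest of the 9 sham and contralateral libraries scored 0.669. LPC_Contra replicate 2 set the next component (-62.9, 13.4% of the variance). Mitochondrially encoded genes took 8.74% to 15.9% of counts, with LNIO_Ipsil replicate 1 highest.

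**Figure D1:**
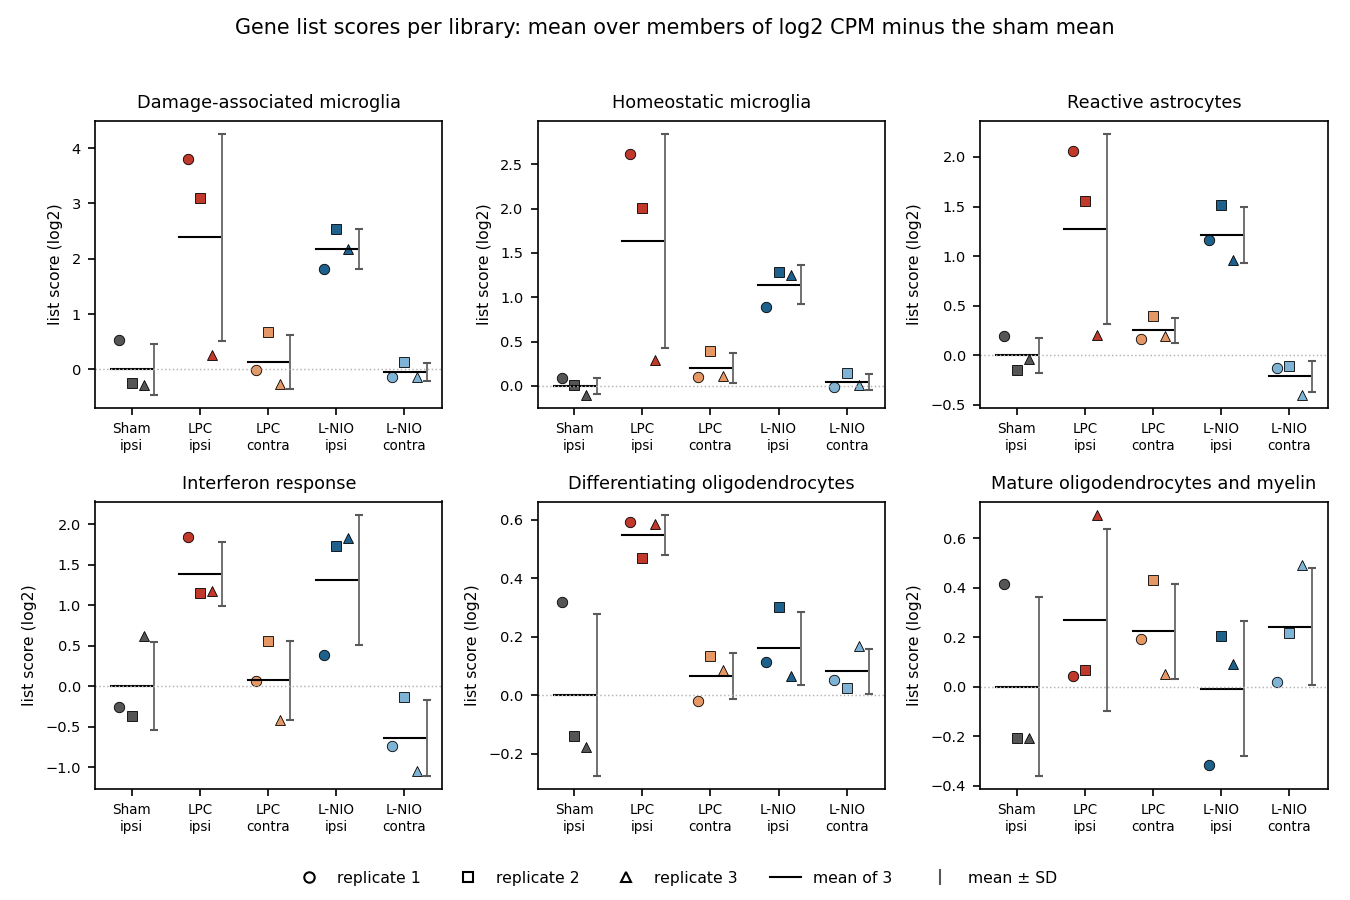
List scores per library for 6 gene lists (y axis, mean over members of log2 CPM minus the sham mean) in the 5 groups (x axis). Symbols are libraries by replicate number, lines the mean of 3 and grey bars the SD; LPC_Ipsil replicate 3 has a damage-associated microglia score of 0.256 against 3.80 and 3.10 in the other LPC_Ipsil libraries.

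The comparison of LPC_Ipsil with Sham_Ipsil asks what demyelinating injury changed at the injection site. Mpeg1, a pore-forming protein of macrophages and microglia, went from 31.7 ± 6.0 to 559 ± 512 CPM (SD, n = 3; log2 fold change 4.14 ± 0.83 SE, edgeR adjusted p = 0.0243). Cst7, a cystatin of activated microglia, rose from 0.502 to 61.5 CPM (log2 6.95 ± 1.44, adjusted p = 0.0245). The chemokine genes Ccl6 (log2 5.30 ± 1.0) and Ccl9 (4.75 ± 0.88), the myeloid kinase gene Fgr (5.71 ± 1.07), the inhibitory receptor gene Pdcd1 (7.35 ± 1.49), Milr1 (4.56 ± 0.93) and Slamf8 (4.18 ± 0.75), both myeloid surface receptors, rose at an adjusted p of 0.0243. Neurod6, a transcription factor of excitatory neurons, fell from 92.2 ± 19.6 to 32.7 ± 8.62 CPM (log2 -1.5 ± 0.34, adjusted p = 0.0262), and Slc17a6, a vesicular glutamate transporter, fell from 20.7 to 5.84 CPM (-1.83 ± 0.46, 0.0373). Also lower were Mas1, an angiotensin-(1-7) receptor gene (-1.29 ± 0.28), Hsd11b1, which regenerates glucocorticoid (-1.46 ± 0.28), Zfp459 (-1.63 ± 0.34), Ctxn3 (-1.86 ± 0.45), Myl1, a muscle myosin light chain (-1.41 ± 0.33), and Grem1, a bone morphogenetic protein antagonist (-2.54 ± 0.69, adjusted p = 0.048).

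In all 871 genes were called, 704 higher and 167 lower, 560 of them by 2-fold or more. In 81.5% of them the 3 libraries of each group did not overlap, as calling genes by the same libraries favours. The smallest adjusted p was that of Nell1, chosen after its values were seen (33.7 ± 1.16 to 17.8 ± 0.495 CPM, log2 -0.92 ± 0.11, edgeR adjusted p = 0.00743). The calls depended on single libraries. Without Sham_Ipsil replicates 1, 2 or 3 the count was 0, 1 and 1, without LPC_Ipsil replicate 1 or 2 it was 0, and without LPC_Ipsil replicate 3 it was 1646, of which 847 were among the 871. Genes at an unadjusted p under 0.05 fell less, from 3391 with all libraries. They were 2969, 2942 and 2842 without Sham_Ipsil replicates 1, 2 and 3, and 1935 and 2659 without LPC_Ipsil replicates 1 and 2. Of the 67 genes named here that were called, 67, 66, 66, 67 and 67 lost their call in those 5 omissions, and 0 without LPC_Ipsil replicate 3. Models of only these groups called 0 genes, limma-trend on FPKM called 2, and DESeq2 called 1471. LPC_Ipsil replicate 3 held Mpeg1 at 55.3 CPM, where replicates 1 and 2 held 1080 and 542.

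Microglial genes rose as a group. Csf1r, the receptor microglia need to survive, went from 77.2 ± 5.88 to 409 ± 273 CPM (log2 2.40 ± 0.45, edgeR adjusted p = 0.0243), with 666, 437 and 123 CPM in the 3 LPC_Ipsil libraries. Cx3cr1, the fractalkine receptor (2.40 ± 0.45), Siglech, a microglial sialic acid receptor (1.57 ± 0.31), Sall1, a microglial identity factor (1.23 ± 0.21), and P2ry12, a purine receptor of resting microglia (1.28 ± 0.33, adjusted p = 0.0403), rose with it. Of 11 homeostatic genes 10 rose over all genes and 11 adjusted over the list alone (median log2 1.70, camera adjusted p = 7.91e-15, adjusted p = 0.177 with an estimated correlation). Of 20 damage-associated genes 15 rose, 5 did not pass, and 18 rose adjusted over the list alone (median 3.37, 6.08e-17, adjusted p = 0.177 with an estimated correlation). Among them were Csf1, a growth factor for microglia (1.38 ± 0.21), Trem2, a lipid-sensing receptor (3.57 ± 0.74; 10.4 ± 4.67 to 124 ± 107 CPM), Ch25h, a cholesterol hydroxylase (5.78 ± 1.23), and Cd68, a lysosomal glycoprotein (3.58 ± 0.75). Spp1, encoding osteopontin, rose by 3.74 ± 0.98 (0.0485), Aif1, encoding the microglial marker IBA1, by 1.98 ± 0.46 (0.0275), and Apoe, the main lipid carrier of the brain, had 1.51 ± 0.42 (0.0517). A rank correlation (rho) with gene length was taken of log2 CPM minus its mean over the other libraries. This rho can follow RNA quality but also the expression changes themselves, and these were not told apart. In the sham libraries rho was 0.224, 0.116 and 0.166. It was -0.134 and 0.0268 in LPC_Ipsil replicates 1 and 2, which held the microglial rise, and 0.217 in replicate 3, which did not. Without LPC_Ipsil replicate 1 the homeostatic median was 1.07 and the damage-associated median 2.60.

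**Figure D2:**
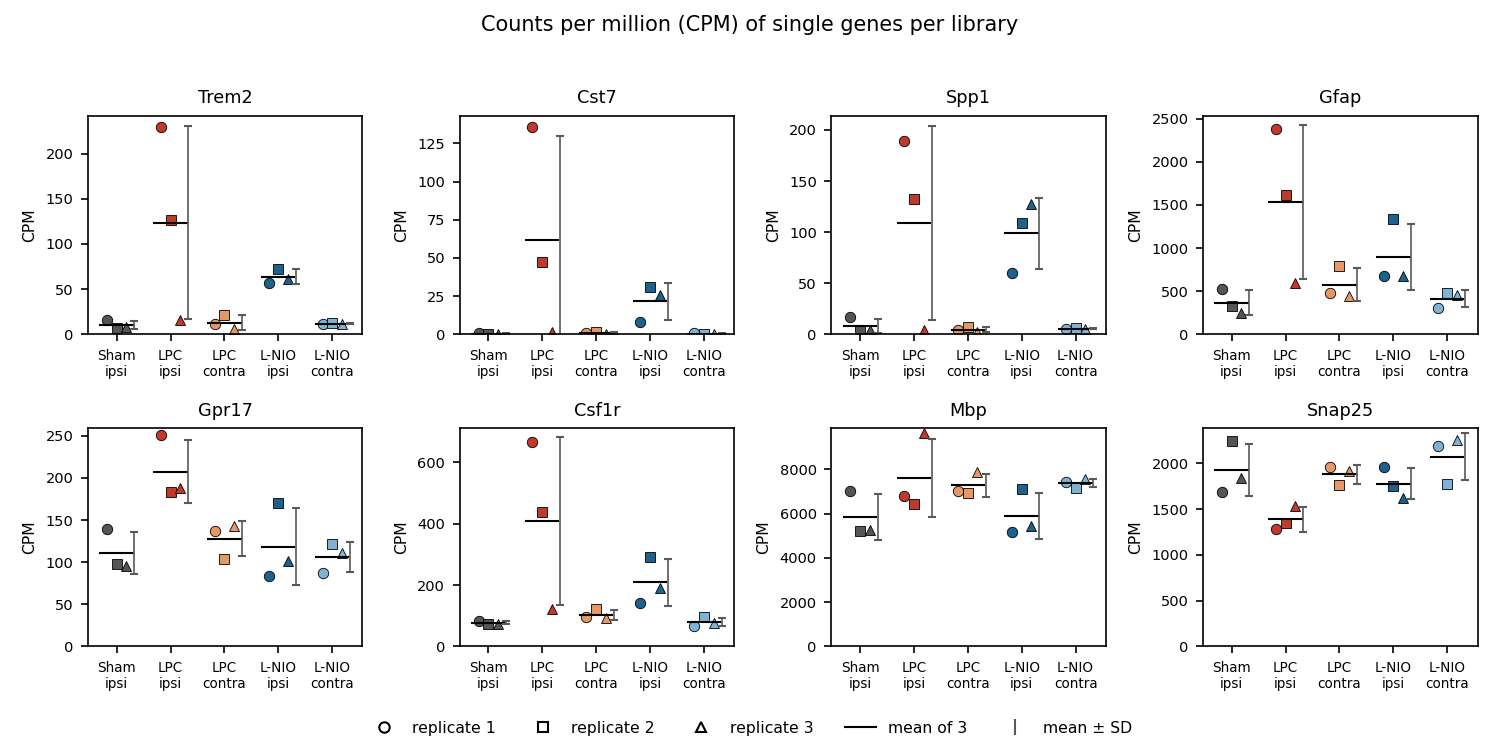
CPM per library (y axis, from 0) of 8 genes in the 5 groups (x axis); symbols are libraries by replicate number, lines the mean of 3 and grey bars the SD. Trem2 averaged 10.4 CPM in Sham_Ipsil, 124 in LPC_Ipsil and 63.7 in LNIO_Ipsil, and Mbp averaged 5840, 7622 and 5895.

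Genes of immune signalling were higher too. Of 12 complement genes 6 rose, 11 adjusted over the list alone (median 2.80, camera adjusted p = 3.46e-10, adjusted p = 0.177 with an estimated correlation). Among these were Itgam, a complement receptor integrin (3.04 ± 0.54), its partner Itgb2 (3.48 ± 0.69) and C3ar1, the C3a receptor (3.83 ± 0.81). MHC class I had 5 of 9 genes higher and 9 adjusted over the list alone (median 2.2, 2.7e-09, adjusted p = 0.177 with an estimated correlation). Examples were B2m, its invariant chain (66.3 ± 15.7 to 305 ± 237 CPM, 2.2 ± 0.48), and Psmb9, an immunoproteasome subunit (2.91 ± 0.58). Interferon response genes rose in 5 of 18 cases, 10 adjusted over the list alone (median 1.17, 8.64e-09, adjusted p = 0.183 with an estimated correlation), with Ifi27l2a up by 3.09 ± 0.71. Chemokines had 5 of 11 higher, 7 adjusted over the list alone (median 2.87, 6.56e-06, adjusted p = 0.177 with an estimated correlation), with Ccl3 at 5.29 ± 1.17 and Cxcl16 at 2.87 ± 0.69. Cytokines had 2 of 8 higher, 6 adjusted over the list alone (median 2.11, 0.000321, adjusted p = 0.183 with an estimated correlation). These were Tgfb1, an anti-inflammatory factor (3.13 ± 0.60), and Osm, a gp130 ligand (3.29 ± 0.85). Without LPC_Ipsil replicate 1 the medians were 1.87 for complement, 1.44 for MHC class I and 2.26 for chemokines.

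Astrocyte and matrix genes followed. Gfap, the intermediate filament of astrocytes, rose from 369 ± 144 to 1531 ± 891 CPM (log2 2.05 ± 0.46, edgeR adjusted p = 0.027). Of 13 reactive astrocyte genes 6 rose and 8 adjusted over the list alone (median 1.45, camera adjusted p = 2.58e-08, adjusted p = 0.177 with an estimated correlation). Examples were Cd44, a hyaluronan receptor (2.12 ± 0.40), Osmr, the oncostatin M receptor (1.45 ± 0.29), and S1pr3 (2.35 ± 0.50). General astrocyte genes had 1 of 11 higher, Aldh1l1 (0.66 ± 0.15), and 4 adjusted over the list alone (median 0.31, 0.00144, adjusted p = 0.289 with an estimated correlation). Matrix and scar genes had 3 of 17 higher and 9 adjusted over the list alone (median 0.84, 1.15e-06, adjusted p = 0.177 with an estimated correlation). They were Sparc, a matricellular protein (137 ± 4.80 to 630 ± 407 CPM, 2.2 ± 0.37), Lox, a collagen cross-linker (2.85 ± 0.60), and Mmp12, the macrophage elastase (4.67 ± 1.17).

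In the oligodendrocyte lineage, Gpr17, a receptor of committed precursors, rose from 111 ± 25.1 to 207 ± 37.6 CPM (log2 0.90 ± 0.25, edgeR adjusted p = 0.048), and Itpr2, a calcium channel of newly forming oligodendrocytes, rose from 29.3 ± 3.37 to 51.8 ± 6.21 CPM (0.83 ± 0.18, 0.0245). These were the 2 of 12 differentiating oligodendrocyte genes called, with 8 adjusted over the list alone (median 0.50, camera adjusted p = 2.94e-06, adjusted p = 0.177 with an estimated correlation). Among precursor genes Cspg4, encoding the proteoglycan NG2 (1.11 ± 0.27), and C1ql1 (1.0 ± 0.25) rose, 2 of 12 and 2 adjusted over the list alone (median 0.31, 0.00484, adjusted p = 0.243 with an estimated correlation), and Pdgfra, the growth factor receptor of these cells, did not pass (0.28 ± 0.14, 0.298). Of 20 myelin genes 0 passed by edgeR, 0 adjusted over the list alone; the list was called higher (median 0.32, 0.0306, adjusted p = 0.642 with an estimated correlation). Mbp, a major myelin protein, had 5840 ± 1038 and 7622 ± 1752 CPM (0.38 ± 0.18, 0.251), and Mog had 0.17 ± 0.26 (0.789). The myelin call was lost without Sham_Ipsil replicate 2 (adjusted p = 0.26), Sham_Ipsil replicate 3 (0.251) or LPC_Ipsil replicate 3 (0.797), within a range of 6.57e-06 to 0.797 over all alternatives. The precursor call was lost without LPC_Ipsil replicate 3 (0.0704, range 0.00103 to 0.243). LPC_Ipsil replicate 3 had a myelin score of 0.695, above the highest of the 9 sham and contralateral libraries (0.49).

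Proliferation genes rose in 4 of 18 cases and 12 adjusted over the list alone (median log2 1.02, camera adjusted p = 2.7e-09, adjusted p = 0.183 with an estimated correlation), among them the replication helicase gene Mcm3 (1.48 ± 0.29), Rrm2, which supplies deoxynucleotides (1.40 ± 0.31), and the mitotic kinase gene Aurkb (1.75 ± 0.41). Lipid efflux and storage genes had 4 of 14 higher, with 11 higher and 1 lower adjusted over the list alone (median 0.96, 4.89e-06, adjusted p = 0.183 with an estimated correlation). They were Lipa, a lysosomal lipase (1.12 ± 0.25), Plin2, a lipid droplet coat protein (1.95 ± 0.43), Npc2, a lysosomal cholesterol carrier (1.58 ± 0.35), and Abca1, a cholesterol exporter (1.5 ± 0.34). Cholesterol biosynthesis was not called (median -0.02, 0.529, 0 of 21 genes by edgeR), and Hmgcs1, an early enzyme of the pathway, had 0.33 ± 0.33 (0.633).

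Neuronal genes fell as a list: 1 of 12 passed, Nefl, the neurofilament light chain (240 ± 50.3 to 161 ± 11.9 CPM, log2 -0.57 ± 0.16, edgeR adjusted p = 0.0485), and 5 adjusted over the list alone (median -0.30, camera adjusted p = 3.38e-05, adjusted p = 0.183 with an estimated correlation). Snap25, a synaptic fusion protein, had -0.47 ± 0.14 (0.0722). Cortical excitatory neuron genes were called lower with Neurod6 alone of 9 passing, 1 adjusted over the list alone (median -0.22, 0.0293, adjusted p = 0.43 with an estimated correlation). The cortical call was lost without Sham_Ipsil replicate 2 (0.13) or LPC_Ipsil replicate 2 (0.116; range 0.00756 to 0.43). Immediate early genes were called lower with 0 of 11 passing by edgeR, 0 adjusted over the list alone (median -0.37, 0.0293, adjusted p = 0.531 with an estimated correlation). This call was lost without Sham_Ipsil replicate 3 (0.516) or LPC_Ipsil replicate 3 (0.252; range 0.000426 to 0.531). Neuroblast genes were called higher with Sox11 (0.66 ± 0.16) alone of 8 passing and 5 adjusted over the list alone (median 0.50, 0.00733, adjusted p = 0.177 with an estimated correlation). The neuroblast call was lost without LPC_Ipsil replicate 3 (0.0704; range 0.00498 to 0.177). With the replicate block the neuroblast list was also higher in uninjected LPC_Contra against sham (median 0.46, camera adjusted p = 0.00485). Between the LPC sides it was not called with that block (0.05, 0.99).

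Vessel genes were called higher. Of 11 endothelial genes 1 passed, Slc2a1, the glucose transporter of the blood-brain barrier (46.6 ± 0.251 to 72.2 ± 3.53 CPM, log2 0.63 ± 0.14, edgeR adjusted p = 0.0262), and 5 adjusted over the list alone (median 0.58, camera adjusted p = 0.000321, adjusted p = 0.254 with an estimated correlation). Cldn5, a tight junction protein, had 0.80 ± 0.26 (0.089) and Nos3, endothelial nitric oxide synthase, 0.30 ± 0.32 (0.661). Pericyte and smooth muscle genes were called with 0 of 9 passing by edgeR, 0 adjusted over the list alone (median 0.49, 0.0164, adjusted p = 0.327 with an estimated correlation). The pericyte call was lost without Sham_Ipsil replicate 2 (0.0555) or LPC_Ipsil replicate 2 (0.0791; range 0.00161 to 0.327). Neither rise was limited to the injured side. With the replicate block, uninjected LPC_Contra was higher than sham for endothelium (median 0.65, camera adjusted p = 2.97e-07) and pericytes (0.53, 0.000165). Between the LPC sides neither list was called with that block (-0.08, 0.491 and -0.14, 0.455). Infiltrating monocyte genes were called with Cd14, a lipopolysaccharide co-receptor (3.02 ± 0.64), alone of 7 passing and 1 adjusted over the list alone (median 0.97, 0.0312, adjusted p = 0.327 with an estimated correlation). That call was lost without LPC_Ipsil replicate 1 (0.0838; range 0.00301 to 0.327). Its median was 1.71 without Sham_Ipsil replicate 1, 1.73 without Sham_Ipsil replicate 3, 2.09 without LPC_Ipsil replicate 3, and 1.61 to 1.67 without any 1 of LPC_Contra replicates 1 to 3, LNIO_Ipsil replicates 2 and 3 and LNIO_Contra replicates 2 and 3. Each omission also changed which genes passed the count filter, with 16988 to 17131 tested in place of 16795. A median can therefore move because other list members were tested, also where the library lies outside the comparison.

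The other lists were not called by camera, with single members that passed. Hypoxia (median 0.01, adjusted p = 0.314) had Hk2, a glycolytic kinase (3.0 ± 0.53), and angiogenesis (0.30, 0.294) had Vwf (1.05 ± 0.27). The integrated stress response (0.18, 0.39) had Atf3 (4.10 ± 0.83), oxidative stress (0.06, 0.302) had Hmox1, a haem-degrading enzyme (1.53 ± 0.41), and T cells (0.19, 0.302) had the costimulatory receptor gene Icos (2.81 ± 0.73), each higher. No member passed by edgeR among MHC class II (median 0.75, adjusted p = 0.113), fibroblasts (0.27, 0.255), border macrophages (0.10, 0.546), striatal neurons (0.34, 0.15), ependyma (-0.05, 0.763), choroid plexus (-1.14, 0.486), red blood cells (0.15, 0.743) or mitochondrially encoded genes (-0.12, 0.15). Col1a1, a fibroblast collagen, had 0.79 ± 0.35 (0.224). Of the lists with under 3 tested members, neutrophils had Csf3r, the granulocyte growth factor receptor, higher (3.23 ± 0.64) as 1 of 2, and 0 of 1 natural killer, 0 of 2 B and plasma cell and 0 of 2 dendritic genes passed by edgeR. The chemokine gene Ccl2 stood at 0.194 CPM in Sham_Ipsil, 0.368 in LPC_Ipsil and 0.598 in LNIO_Ipsil, and Cd3e, a T cell receptor subunit, at 0.163 CPM or less in each library; both were too low to test.

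The comparison of LNIO_Ipsil with Sham_Ipsil asks the same of ischaemic injury. Trem2 had 63.7 ± 8.21 CPM against 10.4 ± 4.67 (SD, n = 3; log2 2.62 ± 0.72 SE, edgeR adjusted p = 0.272), Spp1 99.0 ± 34.7 against 8.16 ± 7.28 (3.60 ± 0.98, 0.272), Cst7 5.44 ± 1.41 on the log2 scale and Clec7a, a beta-glucan receptor, 4.46 ± 1.16 (both 0.263). Of 16795 genes edgeR called 0, with 1489 at an unadjusted p under 0.05, while DESeq2 called 230 and limma-trend on FPKM 1. With LPC_Ipsil replicate 3 left out, a library outside this comparison, edgeR called 398 genes, 386 higher and 12 lower, and with only the groups compared it called 378. Single omissions within the comparison gave 0, and omission of LPC_Contra replicate 2 gave 1. The order of the counts for LPC_Ipsil and LNIO_Ipsil against sham depended on the fit. They were 871 and 0 in the shared model, 1471 and 230 by DESeq2, but 0 and 378 with only the groups compared. The contrast of 871 with 0 therefore does not show that LPC changed more genes than L-NIO.

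As lists, damage-associated microglia rose (16 of 20 adjusted over the list alone, 0 over all genes; median log2 2.37, camera adjusted p = 2.09e-23, adjusted p = 0.106 with an estimated correlation), led by Lgals3, a galectin of phagocytes (2.83 ± 0.75), Clec7a, Cst7 and Tyrobp, the adaptor of Trem2 (3.01 ± 0.79). Homeostatic microglia rose with 10 of 11 adjusted over the list alone and 0 over all genes (median 1.14, 1.19e-13, adjusted p = 0.119 with an estimated correlation), such as Siglech (1.14 ± 0.31) and Csf1r (1.43 ± 0.44). Interferon response genes rose with 10 of 18 adjusted over the list alone and 0 over all genes (median 1.12, 6.32e-14, adjusted p = 0.124 with an estimated correlation). Examples were Ifi27l2a (3.80 ± 0.72), the antiviral synthetase gene Oas1a (3.22 ± 0.73) and the tetherin gene Bst2 (2.30 ± 0.54). Reactive astrocyte genes rose with 7 of 13 adjusted over the list alone and 0 over all genes (median 0.95, 4.37e-12, adjusted p = 0.106 with an estimated correlation), such as Cd44 (1.72 ± 0.40), Lcn2, a secreted siderophore binder (4.42 ± 1.01), and the filament gene Vim (1.95 ± 0.53), with Gfap at 1.28 ± 0.45 (edgeR adjusted p = 0.388). The correlation with gene length was lower in the LNIO_Ipsil libraries (-0.125, -0.102 and 0.101) than in the sham libraries (0.116 to 0.224).

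Complement (7 of 12 adjusted over the list alone, median 2.13, camera adjusted p = 4.31e-14), MHC class I (6 of 9, 1.65, 2.71e-11), chemokines (9 of 11, 2.87, 5.04e-11) and cytokines (3 of 8, 1.76, 1.26e-06) rose as lists, each at an adjusted p = 0.106 with an estimated correlation and with 0 members called over all genes. Examples were Itgam (2.06 ± 0.53), Psmb9 (2.30 ± 0.58), Ccl12 (2.87 ± 0.72), Ccl3 (4.75 ± 1.16) and Il1a (2.05 ± 0.69). Lipid genes (6 of 14 adjusted over the list alone, 0.64, 5.95e-05), matrix genes (3 of 17, 0.22, 0.000918), proliferation (0 of 18, 0.57, 1.8e-07), ependyma (0 of 6, 0.81, 0.000216) and infiltrating monocytes (2 of 7, 0.86, 0.00593) were called higher with an adjusted p = 0.265 with an estimated correlation and 0 members over all genes by edgeR. Their leading members were Apoc1, a lipoprotein subunit (3.95 ± 1.10), Mmp12 (4.25 ± 1.17), Aurkb (1.25 ± 0.41), Tmem212 (1.38 ± 0.55) and Cd14 (2.44 ± 0.64). The chemokine median was 3.51 without Sham_Ipsil replicate 2, and the monocyte median 1.47 without Sham_Ipsil replicate 1. Another 5 called lists each lost their call without at least 1 library. MHC class II (median 1.23, 0.0331) was lost without LPC_Ipsil replicate 3 (0.0617), LPC_Contra replicate 2 (0.0588), LNIO_Ipsil replicate 1 (0.0609) or replicate 2 (0.176, median 0.39; range 0.00737 to 0.336). Astrocytes (0.23, 0.0172) were lost without LPC_Ipsil replicate 3 (0.0569) or LNIO_Ipsil replicate 2 (0.259; range 0.000112 to 0.433). Endothelium (0.20, 0.0243) was lost without LPC_Ipsil replicate 3 (0.078) or LNIO_Ipsil replicate 1 (0.577; range 0.00139 to 0.577). Pericytes (0.34, 0.049) were lost without any 1 of 10 libraries, up to 0.662 without LNIO_Ipsil replicate 1 (range 0.00325 to 0.662). Neurons (-0.20, 0.00864) were lost without Sham_Ipsil replicate 2 (0.209) or LNIO_Ipsil replicate 3 (0.0931; range 6.62e-05 to 0.401). Their adjusted p values were 0.336, 0.433, 0.472, 0.433 and 0.401 with an estimated correlation.

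Of the oligodendrocyte genes Mbp had 5895 ± 1058 CPM against 5840 ± 1038 (log2 0.01 ± 0.18, edgeR adjusted p = 0.992), and Gpr17 0.09 ± 0.24 on the log2 scale (0.95). The myelin (median -0.02, camera adjusted p = 0.859), precursor (0.02, 0.408) and differentiating (0.09, 0.0675) lists were not called. The neuronal gene Snap25 had -0.11 ± 0.14 (0.881).

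LNIO_Ipsil was then set directly against LPC_Ipsil. Gpr17 had a log2 fold change of -0.81 ± 0.25 (edgeR adjusted p = 0.522), the tyrosine kinase gene Fyn -0.27 ± 0.10 and Itpr2 -0.49 ± 0.18 (0.559). edgeR called 0 genes, with 1409 at an unadjusted p under 0.05, DESeq2 called 16 and limma-trend on FPKM 1. Without LPC_Ipsil replicate 3 edgeR called 241, 31 higher and 210 lower, among them P2ry12 at -0.82 (adjusted p = 0.0365) and Cd68 at -1.48 (0.0289). With LPC_Ipsil replicate 1 or 2 left out instead it called 0. Replicate 3 was the LPC_Ipsil library that lacked the microglial rise, so leaving it out raises the LPC_Ipsil mean of microglial genes. That microglial genes were called lower after L-NIO therefore follows in part from the choice of library. The predicted gene Gm8885, chosen after its values were seen, had the smallest adjusted p with all libraries (log2 4.83 ± 0.71, edgeR adjusted p = 0.103; 0.0164 without LPC_Ipsil replicate 3, range 2.4e-06 to 0.773 over all alternatives). It averaged 3.38 CPM in LNIO_Ipsil and 3.07 in LNIO_Contra, against 0.116 in LPC_Ipsil, 0.0584 in LPC_Contra and 0.0786 in Sham_Ipsil, so that it differed between the models on both sides. Gm8885 thus followed the model and not the injured side. The L-NIO libraries may differ from the LPC and sham libraries in more than injury. Comparisons of LNIO_Ipsil with LPC_Ipsil or sham cannot tell such a difference from an effect of injury.

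Of 12 called lists 4 kept their calls in each omission. Differentiating oligodendrocytes (median -0.33, camera adjusted p = 4.22e-05, adjusted p = 0.722 with an estimated correlation) and precursors (-0.19, 0.00438, adjusted p = 0.722 with an estimated correlation; Cspg4 -0.77 ± 0.27) were lower after L-NIO. Striatal neurons were lower (-0.87, 8.95e-05, adjusted p = 0.723 with an estimated correlation) and ependyma higher (0.94, 0.00119, adjusted p = 0.722 with an estimated correlation; Tmem212 1.47 ± 0.55), the latter with a median of 1.56 without LPC_Ipsil replicate 3. In these 4 lists 0 members passed by edgeR, 0 adjusted over the list alone. The damage-associated list was lower (-0.77, 0.0246, adjusted p = 0.868 with an estimated correlation; 1 of 20 adjusted over the list alone, Csf1 -0.84 ± 0.20). That call was lost without LPC_Ipsil replicate 1 (0.382, median -0.12), LPC_Ipsil replicate 2 (0.295) or LNIO_Ipsil replicate 1 (0.0719; range 2.45e-18 to 0.868). Homeostatic microglia were lower (-0.73, 0.00081, adjusted p = 0.842 with an estimated correlation; 1 of 11 adjusted over the list alone, Sall1 -0.73 ± 0.21) and lost their call without LPC_Ipsil replicate 1 (0.674; range 5.32e-24 to 0.842). Another 6 lists lost their call without at least 1 library.

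The LPC and L-NIO responses were compared by their log2 fold changes against the same sham libraries, which correlated at r = 0.788 (covariance 0.273) across genes, where genes are not independent replicates. With each injury set against its own contralateral side, r was 0.741 (covariance 0.205). From mean log2 CPM the covariance was 0.194, and 50 simulations without any effect, sharing the sham libraries, gave 0.054 (r = 0.503), a difference of 0.14. The 3 sham libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. On the same scale, each injury against its own contralateral side gave a covariance of 0.147 (r = 0.736). Those comparisons share no libraries, which argues against shared controls as the only source of the excess. edgeR called 0 genes in both comparisons, with 3391 and 1489 genes at an unadjusted p under 0.05. Without LPC_Ipsil replicate 3, 378 genes were called higher in both (30.2 from independent lists) and 10 lower in both (0.214 from independent lists), chance numbers that take no account of the shared sham libraries. With each injury against its own contralateral side and the same library left out, 360 genes were called in both, all higher (20 from independent lists).

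LPC_Ipsil against LPC_Contra compares the injured tissue with its own contralateral side. The microglial genes P2ry12 (56.7 ± 2.49 to 168 ± 90.0 CPM, log2 1.57 ± 0.33), Csf1r (1.99 ± 0.44) and Cx3cr1 (2.02 ± 0.45) and the damage-associated genes Cst7 (6.27 ± 1.36), Ch25h (6.87 ± 1.37) and Gpnmb, a lysosomal glycoprotein (5.29 ± 1.18), each had an edgeR adjusted p of 0.0629. So edgeR called 0 genes, with 2036 at an unadjusted p under 0.05, DESeq2 called 669 and limma-trend on FPKM 0 and 1 for its 2 pseudocounts. Without LPC_Ipsil replicate 3 edgeR called 950, 901 higher and 49 lower. With the replicate block, a pairing that the LPC libraries did not settle, it called 32, 28 higher and 4 lower.

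Of the 22 lists called 17 kept their calls in each omission, with 0 members over all genes by edgeR. Damage-associated (median 3.09, camera adjusted p = 3.64e-22, 19 of 20 adjusted over the list alone) and homeostatic microglia (1.64, 1.45e-17, 11 of 11), complement (2.52, 7.89e-13, 11 of 12; Itgam 2.52 ± 0.52), interferon response (1.35, 1.91e-12, 10 of 18; Ifi44 1.92 ± 0.45), lipid efflux and storage (1.20, 7.17e-09, 8 of 14; Abca1 1.56 ± 0.34) and differentiating oligodendrocytes (0.45, 8.76e-07, 8 of 12; Rras2 0.78 ± 0.16, Itpr2 0.86 ± 0.18) were higher. So were reactive astrocytes (1.10, 1.33e-07, 7 of 13; Cd44 1.78 ± 0.40), MHC class I (1.56, 1.98e-07, 7 of 9), matrix (0.72, 4.2e-07, 8 of 17; Lox 3.04 ± 0.61), fibroblasts (0.80, 0.000391, 3 of 8; Col6a3, a collagen, 1.20 ± 0.30) and red blood cells (0.85, 0.000348, 2 of 4; Alas2, of haem synthesis, 1.12 ± 0.32). Lower were neurons (-0.33, 8.69e-07, 3 of 12; Snap25 -0.44 ± 0.14) and immediate early genes (-0.63, 8.76e-07, 3 of 11; Egr1 -0.90 ± 0.18). Each of these had an adjusted p = 0.143 with an estimated correlation. Chemokines (2.85, 5.33e-05, 7 higher and 1 lower of 11; Ccl6 4.38 ± 0.93), proliferation (0.63, 4.98e-06, 1 of 18; Mcm3 1.04 ± 0.29), cytokines (1.61, 0.000386, 4 of 8; Osm 3.86 ± 0.90) and infiltrating monocytes (1.72, 0.00367, 3 of 7; Cd14 2.39 ± 0.62) were higher with adjusted p values of 0.143, 0.274, 0.169 and 0.172 with an estimated correlation. Without LPC_Ipsil replicate 1 the medians were 2.37 for damage-associated microglia, 0.42 for monocytes, 0.94 for MHC class I, 1.78 for complement and 2.23 for chemokines. The monocyte median was 1.01 without LPC_Contra replicate 1, and the chemokine median 2.26 without LPC_Contra replicate 1 and 3.54 without LPC_Contra replicate 2. The myelin list was not called (0.06, 0.945). With the replicate block, endothelium (-0.08, camera adjusted p = 0.491), pericytes (-0.14, 0.455), neuroblasts (0.05, 0.99) and astrocytes (0.08, 0.244) were not called either. All of these lists were called higher in LPC_Ipsil against sham.

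LNIO_Ipsil against LNIO_Contra makes the same comparison for L-NIO. The interferon genes Ifi27l2a (10.5 ± 7.73 against 0.407 ± 0.194 CPM, log2 4.64 ± 0.77), Ifi44 (2.44 ± 0.46) and Bst2 (2.63 ± 0.55) each had an edgeR adjusted p of 0.186, the smallest in this comparison and shared with other genes. Lcn2 was at 4.31 CPM in LNIO_Ipsil and at 0 in each LNIO_Contra library. edgeR called 0 genes, with 1021 at an unadjusted p under 0.05, DESeq2 called 186 and limma-trend on FPKM 0. With LPC_Ipsil replicate 3, outside this comparison, left out, edgeR called 380 genes, all higher. It called 359 with only the groups compared, with the replicate block 6, and without LNIO_Ipsil replicate 1 it called 1.

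The interferon list (median 2.17, camera adjusted p = 3.51e-37, 17 of 18 adjusted over the list alone, 0 over all genes) and the chemokine list (3.16, 3.13e-16, 9 higher and 1 lower of 11; Ccl12 3.80 ± 0.78, Ccl3 6.25 ± 1.34) kept their calls at an adjusted p = 0.0288 with an estimated correlation. With the replicate block as well, both had an adjusted p = 0.116 with an estimated correlation. Damage-associated microglia (2.46, 2.49e-29, 16 of 20 adjusted over the list alone; Spp1 4.14 ± 1.01, Cst7 5.60 ± 1.42), complement (1.96, 6.3e-17, 7 of 12; C3ar1 3.05 ± 0.80) and MHC class I (1.61, 4.21e-13, 6 of 9; B2m 1.72 ± 0.48) were higher at an adjusted p = 0.0676 with an estimated correlation. Reactive astrocytes (1.11, 6.04e-17, 9 of 13 adjusted over the list alone; Cxcl10, an interferon-induced chemokine, 3.17 ± 0.71) had an adjusted p = 0.0618 with an estimated correlation. Homeostatic microglia (1.07, 1.26e-15, 9 of 11; P2ry12 0.99 ± 0.33), MHC class II (1.13, 9.71e-05, 2 of 7; H2-Aa 1.70 ± 0.52) and fibroblasts (0.85, 1.08e-05, 3 of 8; Col1a2, a collagen, 1.04 ± 0.32) had an adjusted p = 0.0765 with an estimated correlation. Lipid genes (0.64, 1.22e-06, 4 of 14), matrix (0.23, 1.1e-06, 3 of 17; Sparc 1.16 ± 0.36), cytokines (1.05, 5.02e-05, 4 of 8) and monocytes (1.18, 0.000106, 1 of 7) were higher, with adjusted p values of 0.141, 0.091, 0.121 and 0.091 with an estimated correlation. Striatal neurons (-0.80, 3.88e-06, 0 of 9; Tac1, a tachykinin precursor, -0.80 ± 0.39) and neurons (-0.21, 0.000699, 0 of 12) were lower, both at an adjusted p = 0.236 with an estimated correlation. With Lcn2 and the chemokine gene Cxcl13, both at 0 in LNIO_Contra, set at a bound of 3 counts over that group, the medians of their lists stayed at 1.11 and 3.16. The striatal median was -1.40 without LNIO_Ipsil replicate 2. These 15 lists kept their calls in each omission, and 7 more did not. Among the 7 was myelin (-0.22, 0.000235, 0 of 20 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation), lost without LNIO_Ipsil replicate 1 (0.133) or LNIO_Contra replicate 3 (0.109; range 1.26e-06 to 0.506). Another was astrocytes (0.05, 0.0333, adjusted p = 0.511 with an estimated correlation), lost with the replicate block (0.0818) and without any 1 of 5 libraries, up to 0.645 without LNIO_Ipsil replicate 2 (range 9.2e-05 to 0.645).

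The contralateral sides were set against sham to ask whether injury changed distant tissue. Sham tissue was a saline injection site and contralateral tissue was not injected. In LPC_Contra and LNIO_Contra alike, side and injection therefore differed from sham as well as injury, and these cannot be told apart. Tnfaip8l3, a phosphoinositide carrier gene, fell in LPC_Contra from 15.2 ± 2.70 to 4.62 ± 0.904 CPM (SD, n = 3; log2 -1.72 ± 0.22, edgeR adjusted p = 0.0224), the 1 gene called, with 1624 at an unadjusted p under 0.05. It stood at 6.60 CPM in LPC_Ipsil, 6.14 in LNIO_Ipsil and 6.90 in LNIO_Contra, so the sham libraries were the highest. The count was 0 without Sham_Ipsil replicate 1 or 2 or LPC_Contra replicate 1 or 2, with only the groups compared and with the replicate block, and 2 without LPC_Contra replicate 3. DESeq2 called 28 genes. Of 11 lists 3 kept their calls in each omission, all higher: endothelium (median 0.66, camera adjusted p = 1.01e-07, 7 of 11 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation; Slc2a1 0.72 ± 0.14, Cldn5 0.91 ± 0.26), pericytes (0.54, 0.000208, 1 of 9 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation) and neuroblasts (0.46, 0.00307, 3 of 8 adjusted over the list alone, adjusted p = 0.286 with an estimated correlation). LPC_Contra replicate 2 had a fall of counts with gene length (rho = -0.489, other libraries -0.243 to 0.273).

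In LNIO_Contra against Sham_Ipsil edgeR called 0 genes, with 457 at an unadjusted p under 0.05, DESeq2 called 2 and limma-trend on FPKM 1. Of 7 lists called 1 kept its call in each omission, interferon response, which was lower (median -0.71, camera adjusted p = 8.81e-07, 3 of 18 adjusted over the list alone, adjusted p = 0.908 with an estimated correlation). Ifit1, an RNA-binding interferon effector, had 1.40 ± 0.985 CPM against 5.40 ± 4.90 (log2 -1.93 ± 0.60, edgeR adjusted p = 1) and Ifi44 -1.54 ± 0.46.

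LNIO_Contra against LPC_Contra compares the uninjected sides. edgeR called 0 genes, with 576 at an unadjusted p under 0.05, DESeq2 called 6 and limma-trend on FPKM 1, and without LPC_Contra replicate 2 edgeR called 2. Of 14 lists called 3 kept their calls in each omission, all lower in LNIO_Contra: endothelium (median -0.56, camera adjusted p = 8.43e-13, 6 of 11 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation), angiogenesis (-0.59, 4.01e-05, 2 of 9 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation) and interferon response (-0.72, 2.31e-07, 0 of 18 adjusted over the list alone, adjusted p = 0.439 with an estimated correlation). The vascular growth factor receptor genes Flt1 (-1.08 ± 0.31) and Kdr (-1.16 ± 0.32) and Slc2a1 (-0.56 ± 0.14) were examples, each with an edgeR adjusted p of 1.

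The interaction of model and side tests whether the difference between sides differed between L-NIO and LPC. edgeR called 0 genes, with 171 at an unadjusted p under 0.05, and DESeq2 and limma-trend on FPKM also called 0. Of 18 lists called 4 kept their calls in each omission. The interaction was positive for interferon response (median 0.62, camera adjusted p = 6.25e-07, adjusted p = 0.445 with an estimated correlation; Ifi27l2a 2.15 ± 1.01). Between the injured sides the interferon list was not called (LNIO_Ipsil against LPC_Ipsil, median 0.004, camera adjusted p = 0.941), and between the contralateral sides its median was -0.72. The interaction was also positive for immediate early genes (0.56, 2.31e-07, adjusted p = 0.343 with an estimated correlation; Egr1 0.65 ± 0.25), with medians of -0.63 between LPC sides and -0.13 between L-NIO sides, and for ependyma (1.03, 8.11e-06, adjusted p = 0.343 with an estimated correlation; Tmem212 1.64 ± 0.74), with medians of -0.67 and 0.235. It was negative for differentiating oligodendrocytes (-0.29, 1.78e-07, adjusted p = 0.343 with an estimated correlation; Rras2 -0.58 ± 0.23, Itpr2 -0.59 ± 0.26), with medians of 0.445 and 0.152. In these 4 lists 0 members passed by edgeR, 0 adjusted over the list alone. The reactive astrocyte list was called higher while its median was -0.07 (0.0253, adjusted p = 0.664 with an estimated correlation), and it lost the call without any 1 of 7 libraries, up to 0.197 without LPC_Ipsil replicate 3 (range 7.53e-07 to 0.931).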

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

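Fits with voom quality weights, omissions of LPC_Ipsil replicate 3 or LPC_Contra replicate 2 from comparisons they lie outside, and omissions from the overlap were chosen after results were seen; the other settings were planned. Comparisons are given in the order LPC_Ipsil, then LNIO_Ipsil against sham, LNIO_Ipsil against LPC_Ipsil, LPC sides, L-NIO sides, LPC_Contra, then LNIO_Contra against sham, LNIO_Contra against LPC_Contra, and the interaction. Except where a setting tests other genes or fewer libraries, the cause was not tested. The interaction stayed at 0 genes by edgeR, DESeq2 and limma (171 at an unadjusted p under 0.05), and DESeq2 factors in edgeR moved no count by over 1.5 times.

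LPC_Ipsil against sham called 871 genes, 524 without a filter, 1471 by DESeq2, 0 with only the groups compared, 2 on FPKM with each pseudocount, 4567 with voom weights, and 0 to 1646 over single omissions. The stricter filter called 871 with 71.8% higher in place of 80.8%. LNIO_Ipsil against sham went from 0 by edgeR (1489 at an unadjusted p under 0.05) to 1 without a filter, 230 by DESeq2, 378 with only the groups compared, 1 on FPKM with each pseudocount, 1 with voom weights, and 0 to 398 over omissions. LNIO_Ipsil against LPC_Ipsil went from 0 by edgeR (1409 at an unadjusted p under 0.05) to 1 without a filter, 16 by DESeq2, 1 on FPKM with each pseudocount, 580 with voom weights, and 0 to 241 over omissions.

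The LPC sides went from 0 by edgeR (2036 at an unadjusted p under 0.05) to 669 by DESeq2, 1 on log2(FPKM + 0.1), 1856 with voom weights, and 0 to 950 over omissions. The L-NIO sides went from 0 (1021) to 186 by DESeq2, 359 with only the groups compared, and 0 to 380 over omissions. LPC_Contra against sham, with 1 gene called, had 28 by DESeq2, 0 by edgeR with only the groups compared (1624 at an unadjusted p under 0.05 in the full model), 2 on log2(FPKM + 0.1), and 0 to 2 over omissions. LNIO_Contra against sham went from 0 by edgeR (457) to 1 without a filter, 2 by DESeq2, 3 with only the groups compared, 1 on FPKM with each pseudocount and 1 with voom weights. LNIO_Contra against LPC_Contra went from 0 by edgeR (576) to 1 without a filter, 6 by DESeq2, 1 on FPKM with each pseudocount, 1 with voom weights, and 0 to 2 over omissions.

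With the replicate block the counts were 652, 1, 0, 32, 6, 0, 1, 1 and 0 in that order by edgeR. By the correlation of deviations only the L-NIO numbers met the rule for pairing. In the LPC groups same-numbered deviations correlated at -0.0357, 0.165 and 0.334, LPC_Ipsil replicate 1 correlated better with LPC_Contra replicate 2 (0.24), and the labels give these libraries no more than a shared number. High and low gene states, examined later, pair LPC replicates 1 and 2 by number (26 and 27 of 27 shared) and leave replicate 3 undecided, so for the LPC sides the value with the block, 32 genes (28 higher, 4 lower), stands beside 0 without it. The block ended 4 of 146 list calls: pericytes in LNIO_Ipsil against sham (adjusted p from 0.049 to 0.0561), damage-associated microglia in LNIO_Ipsil against LPC_Ipsil (0.0246 to 0.0812), astrocytes between L-NIO sides (0.0333 to 0.0818) and fibroblasts in LNIO_Contra against sham (0.0397 to 0.0919). It added MHC class II in LPC_Ipsil against sham (0.113 to 0.0494), striatal neurons (0.0549 to 0.0437) and cholesterol biosynthesis (0.0549 to 0.0449) in LNIO_Ipsil against sham, and striatal neurons between LPC sides (0.056 to 0.000179). With an estimated correlation and the block, 0 lists were called by camera in any comparison. It changed no other list call, and of the 67 called genes named for LPC_Ipsil against sham 8 lost their call with it.

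With an estimated correlation camera called 0 lists in each comparison except the L-NIO sides, where it called 2. By fry 18 lists were called in LPC_Ipsil against sham, 2 between the L-NIO sides and 0 elsewhere. Leaving LPC_Ipsil replicate 3 out, camera with an estimated correlation called 9, 9, 1, 10, 11, 0, 0, 0 and 1 lists. Over single omissions the number of lists called ran from 8 to 20 (LNIO_Ipsil against LPC_Ipsil), 4 to 9 (LNIO_Contra against sham), 8 to 14 (LNIO_Contra against LPC_Contra) and 8 to 19 (interaction), and stayed within 1.5 times elsewhere. Lists whose test changed direction in an omission had these ranges of the median: myelin 0.0492 to 0.539 in LPC_Ipsil against sham and -0.445 to -0.123 in LNIO_Ipsil against LPC_Ipsil, damage-associated microglia -1.24 to -0.119 in the latter, and striatal neurons -0.186 to 0.879 in LNIO_Contra against sham. In the interaction they were homeostatic microglia -0.97 to -0.106, reactive astrocytes -0.398 to 0.383, choroid plexus -0.838 to 2.7 and mitochondrially encoded genes -0.0804 to 0.353. Of 2628 tests of called lists, 2156 kept the call, 463 lost it and 9 changed direction.

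Across genes the correlation of the LPC and L-NIO responses ran from 0.581 without LPC_Ipsil replicate 1 to 0.785 without LNIO_Ipsil replicate 1. Genes called in both were 0 by edgeR with all libraries (3391 and 1489 at an unadjusted p under 0.05) and 388 without LPC_Ipsil replicate 3. Of 1075 tests of called named genes 503 kept the call, 572 lost it and 0 changed direction among them; of 3610 tests of named genes that were not called 222 were called. At this depth 1 CPM stood for 15 to 21 counts, so genes far under 1 CPM, such as Ccl2, had too few counts to test.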

Other observations

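The gene families, both patterns and their tests were chosen after the results were seen; only the splits of the libraries were planned. The families were not tested for enrichment. In LPC_Ipsil against sham 5 of 6 Fc gamma receptor genes were higher (median log2 fold change 2.81), as were 9 of 13 cathepsins, the lysosomal proteases (1.82), 4 of 10 Toll-like receptors (1.76), 3 of 4 Siglecs (2.85) and 4 of 7 Cd300 receptors (2.70), by edgeR over all genes, where 704 of 16795 were higher. Also called higher were 1 of 5 Ms4a genes (median 2.14), 1 of 5 paired immunoglobulin-like receptors (2.04), 2 of 14 C-type lectins (0.44) and 5 of 28 integrins (0.30), and without LPC_Ipsil replicate 3 the former 2 families had 4 of 5 and 5 of 5. Subunits of the vacuolar proton pump, which acidifies the same lysosomes, had 0 of 17 called by edgeR and a median of -0.08. Receptors for glutamate and GABA had 6 of 37 lower (median -0.34). These calls share the dependence on single libraries of the 871 called genes, which fell to 0 without LPC_Ipsil replicate 1.

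In LNIO_Ipsil against sham the same families had 0 genes called by edgeR, with medians of 2.44 for Fc gamma receptors, 1.08 for cathepsins and 0.97 for Toll-like receptors. Without LPC_Ipsil replicate 3, 5 of 6, 7 of 13 and 2 of 10 of them were called higher. In the direct comparison of LNIO_Ipsil with LPC_Ipsil without that library, 6 of 13 cathepsins were called lower after L-NIO (median -1.09). With all libraries edgeR called 0 of 13 (median -0.64). The library left out was the LPC_Ipsil library that lacked the microglial rise, so the calls follow in part from that choice.

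LPC_Ipsil replicate 3 scored 0.256 for damage-associated microglia, where replicates 1 and 2 scored 3.80 and 3.10. Against a swap with a sham or contralateral library, the highest of those 9 scored 0.669 and the lowest of the other 5 injected-side libraries scored 1.82. For even dilution with unlesioned tissue, its interferon score of 1.18 was set against all 9 and lay above them (-1.05 to 0.625). It kept 78.7% of the rise of the other LPC_Ipsil libraries, against 7.42% for damage-associated microglia. The interferon list was picked after the scores were seen and varied widely between unlesioned libraries. It therefore cannot decide whether this library was diluted. A library of another mouse under this label stays open: of 27 high or low gene states it shared 21 with LPC_Contra replicate 3 and at most 18 with another library, but without Cwc22 and its 6 copies, which move together, 14 of 20 against 13, and under 2 of 6 gene rules another library shared more. What kept this library near sham stays open too, and no biological explanation was tested.

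Some genes were either high or low in a library with a wide gap between, and same-numbered injured-side and contralateral libraries shared these states. The gene rule, a gap of 2 on the log2 scale with 8 genes that follow the choroid plexus list left out, was picked after the values were seen among 6 such rules. Under it the same-number pairing shared 93.2% of the states of 27 genes, more than any other of 720 pairings (exact permutation p = 0.00139). The 6 rules gave exact permutation p values of 0.00139 to 0.00278. The own number was best for 4 to 6 of the 6 injured-side libraries. It was tied for 1 under 2 rules and behind another for 1 under 3 rules. Many of the 720 pairings join an LPC with an L-NIO library, which cannot be one mouse. Gm8885, among the 27 genes, was high in all 6 L-NIO libraries and in 0 others. These p values therefore also count differences between the models. The 720 include every pairing within models, and under the rule used the same-number pairing shared more states than each of these. No p value was computed over the pairings within models alone. Against all libraries of a group being technical replicates of one mouse, the most different pair of each group differed in 9 to 13 of the 20 genes without Cwc22 and its copies, where same-numbered libraries differed in at most 6; against a batch by number, same-numbered libraries of different models shared 51.7% and differently numbered ones 54.9% (difference -3.24 percentage points). Equal numbers marking one mouse would fit these shared states, with LPC_Ipsil replicate 3 undecided, and would make the side comparisons paired ones. Over the same 720 pairings, with the same limit, the exact permutation p was 0.00139 also without Cwc22 and its copies.

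Each comparison of 3 libraries with 3 has 10 splits, which cannot give a share under 0.1. LPC_Ipsil against sham called 871 genes by edgeR and the highest other split 0, so 1 of 10 was as large. LPC_Contra against sham called 1 gene and the highest other split 0, again 1 of 10. In the other 7 comparisons edgeR called 0 genes in the real split, so all 10 were as large; their counts at an unadjusted p under 0.05 ran from 171 to 2036, and DESeq2 called 0 to 669. The highest other split called 59 genes for LNIO_Ipsil against sham, 228 for LNIO_Ipsil against LPC_Ipsil, 1094 for LPC_Ipsil against LPC_Contra, 241 for LNIO_Contra against LPC_Contra and 0 for the other 3.

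The split with 59 exchanged Sham_Ipsil replicate 1 and LNIO_Ipsil replicate 2. The split with 1094 exchanged LPC_Ipsil replicate 3 and LPC_Contra replicate 2, the one with 228 exchanged LPC_Ipsil replicate 3 and LNIO_Ipsil replicate 2, and the one with 241 exchanged LPC_Contra replicate 2 and LNIO_Contra replicate 2. Splits that call this many genes point to a structure of the samples, in which LPC_Ipsil replicate 3 or LPC_Contra replicate 2 takes part in the latter 3 and neither in the split with 59. LPC_Contra replicate 2 also had 1513 CPM of the ribosomal RNA gene Rn18s, where the other libraries had 348 to 723.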
